A study of Mus musculus with 8 samples.

How the data were processed

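Polyadenylated RNA from mouse bone marrow cells was sequenced in 8 libraries of 5 groups: MDP (1 library), cMoP (2), Ly6Chi monocytes (2), Ly6Clo monocytes (1) and Ly6Chi monocytes with a knockout of Upf2 (2). The labels conflict on the cells: their source names give bone marrow, followed here, and their cell type tag gives a monocytic cell line. In this field MDP stands for the monocyte-dendritic cell progenitor and cMoP for the common monocyte progenitor, successive bone marrow precursors of monocytes. Ly6Chi and Ly6Clo monocytes carry much or little of the surface protein Ly6C. Upf2 encodes a core factor of nonsense-mediated decay (NMD), which degrades transcripts with premature stop codons. The cMoP and Ly6Chi controls are described as floxed. RNA of an integrity number over 7 was made into strand-specific TruSeq libraries, per the labels' protocols, and sequenced as read pairs of 100 bp. The labels gave each library its group. Nothing in them says that replicates came from separate animals, so p-values measure only the spread between these samples, which can be technical.

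The authors used FastQC, Trimmomatic, STAR 2.5.2a and RSEM, and listed mm10 (beside a human build), per the submitters' processing notes. Order and settings of these steps were not given in the sources used here. The deposited expression table of 48709 genes is named for FPKM, yet its columns sum to 1000000 (999999 in Ly6Chi replicate 1), as TPM does but for rounding and FPKM does not. Its values were therefore treated as TPM, a measure of transcript abundance, and the test planned for FPKM was applied to TPM without other change. The authors deposited a further table per library with 1 intron per line, and the program that made it was not given in the sources used here. In these tables the deposited whole-number counts are reads across the left and right exon-intron boundary and spliced reads at either end of the intron. The deposited signal is a trimmed mean of read coverage over the intron, not scaled to the library. The deposited fraction, called retention ratio below, is that coverage divided by the coverage plus the larger spliced count. It was recomputed from the other columns within 0.0001 for at least 95.2% of the introns of each library. Because the ratio rests on coverage over the whole intron, it can stay low where many reads cross only 1 boundary. The knockout tables list 204370 introns, of which 36004 are marked as overlapping or lying near an antisense gene. The tables of the other 6 libraries list 205984 introns and carry no such mark. The 204362 introns common to all tables were used, and 166494 of them (81.5%) are unmarked in both lists. Introns marked as overlapping a known exon or an antisense gene were left out of the comparisons.

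Expression was compared with limma (lmFit, eBayes with a trend) on log2(TPM + 1), over the 13126 genes with at least 1 TPM in at least 2 libraries. Fold changes given as log2 are on this scale, which understates the change of low genes, and folds without log2 are ratios of mean TPM. Retention was compared with edgeR's quasi-likelihood test on the counts as deposited. For each intron, U was the sum of left and right boundary reads, S the larger of the spliced counts at the left and right end, and the tested value the change of U relative to S. The 48132 introns tested, in 6785 genes, had U + S of at least 20 in every library and U of at least 20 over all libraries. All 8 libraries entered each fit and shared 1 estimate of the spread, which rests on 3 residual degrees of freedom among libraries. MDP and Ly6Clo have 1 library each and were assumed to vary like the replicated groups. P-values were adjusted by Benjamini and Hochberg, and adjusted values under 0.05 passed. The comparisons were cMoP with MDP, Ly6Chi with cMoP, Ly6Clo with Ly6Chi, and knockout with control Ly6Chi. A further test asked which introns varied over the 4 control stages. The main design keeps any overall shift of U relative to S between groups, and an alternative removes it by TMM scaling of U and S apart. Intron positions are on mm10 as in the files, 1-based, and 99.9% of the tested introns match introns of GENCODE mouse release 21, from which exon numbers and coding or untranslated places were taken. An intron was called one-ended when the smaller boundary count was under 0.25 of the larger one in the group with more reads.

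The gene lists, the comparisons, their tests and most alternatives were chosen before the data were examined. The 24 lists hold genes of progenitors, granule proteases and cMoP, the cell cycle, Ly6Chi and Ly6Clo monocytes, NMD factors, NMD targets, amino acid and integrated stress, splicing regulators, the core spliceosome, interferon response, p53 targets, inflammation and immediate-early response, antigen presentation, lysosome and phagocytosis, ribosome biogenesis, and markers of neutrophils, B and plasma cells, T and NK cells, erythroid cells, dendritic cells, macrophages, eosinophils with basophils and mast cells, and megakaryocytes with platelets. Lists were tested with limma's camera (preset correlation 0.01), which sets a list against all other genes, and again with an estimated correlation. Lists with fewer than 3 measured members were not tested. List counts adjusted over the list alone use the p-values of that list only. Among calls whose groups did not overlap, the rule for named genes took the 5 largest rises and the 5 largest falls of each comparison, passing over unnamed gene models. It added 2 to 4 members per list with the smallest p, Upf2 and the NMD factors in the knockout comparison, and the 5 introns with the highest mean retention ratio. Some of the genes and introns chosen in these ways are not reported here. The Ly6Chi list has 27 measured entries because Itgam stands under 2 identifiers. Retention changes were correlated with expression changes across genes by permutation tests with 100000 resamples. RSEM divides reads between near-identical genes by estimation, so values of genes with close copies (Ly6c2 with Ly6c1, Lyz1 with Lyz2, Sirpb1c, Ifit3 with Ifit3b, Chil3) are uncertain, as are small RNAs inside host genes (Mir142b, Mir6418, Snord22).

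The tests were tried on simulated data made from means over all 8 libraries, with changes put into the knockout group. Noise was drawn apart for each gene or intron in each library, so no shift common to a library was simulated. With 200 of 48132 introns changed, the retention test recovered 0% of changes of 2-fold, 32.5% of 4-fold and 74% of 8-fold, and 3.27% of its calls at 8-fold were false. The changed introns were drawn only from those with a mean U of at least 5. The spread of the simulated counts was a fixed value, not estimated from these data. The shares recovered therefore do not hold for all tested introns. With 200 of 13126 genes changed, the expression test recovered 36% of changes of 2-fold and 89.5% of 4-fold, and 5.79% of its calls at 4-fold were false. Shares of introns carry Wilson confidence intervals of 95%. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Alternatives were another pseudocount (0.1), no filter or a minimum of 5 TPM, quantile and median scaling, other read minimums (10, 50), TMM scaling, every intron class, only introns without a warning, intron depth in limma, DESeq2, only the 2 groups compared, a replicate block, and each replicate left out in turn. Others were added after the data were seen. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The quantitative PCR named in the labels was not analysed here.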

Results

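Gene expression and intron retention were measured in polyadenylated RNA from mouse bone marrow cells, in 8 libraries of 5 groups. MDP and Ly6Clo monocytes have 1 library each and no replicate. The cMoP, the control Ly6Chi monocytes and the Ly6Chi monocytes with a knockout of Upf2, called the knockout here, have 2 each. The title of the series places the question in the part intron retention plays in how mouse monocytes mature and work. The expression table gives no counts, so depth is given from the intron tables, as sums over the introns listed. Spliced reads totalled 29100467 in MDP, 36887070 and 37833159 in cMoP replicates 1 and 2, 31388146 and 34202084 in Ly6Chi, 28925018 in Ly6Clo, and 32868473 and 31397848 in the knockout. Reads across exon-intron boundaries totalled 2619816 in MDP, 3069450 and 2302466 in cMoP, 2939383 and 3250158 in Ly6Chi, 3353268 in Ly6Clo, and 2786112 and 2780279 in the knockout. Per 100 spliced reads, boundary reads numbered 6.09 in cMoP replicate 2 and between 8.32 and 11.6 in the other libraries. Genes with at least 1 TPM numbered between 11106 (cMoP replicate 2) and 12635 (MDP). Replicates correlated across genes on log2 TPM with a Pearson r of 0.973 in cMoP, 0.988 in Ly6Chi and 0.987 in the knockout.

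Upf2 (ENSMUSG00000043241), the targeted gene, was read at similar TPM in knockout and control, with fewer reads at its start in the knockout. Its TPM was 23.1 in MDP, 19.7 and 18.8 in cMoP, 20.2 and 18.2 in control Ly6Chi, 19.2 in Ly6Clo, and 20.4 and 22.5 in the knockout. Spliced reads from exon 2 (2:5957471–5957850, mm10) to exon 3 (2:5960933–5961712, 780 bp, coding throughout), the exons the labels name for their quantitative PCR, numbered 10 and 13 in the knockout and 41 and 45 in control Ly6Chi. Set against the median of the 18 later junctions of Upf2, this junction stood at 13.5% in the knockout, 53.3% in control Ly6Chi, 40% and 21.5% in cMoP replicates 1 and 2, 59% in MDP and 49.4% in Ly6Clo. A lean of reads to the 3′ end also lowers this value, and the median log2 ratio of 3′ to 5′ spliced reads was 1.36 and 1.00 in the knockout, 0.61 and 0.70 in control Ly6Chi and 1.45 in cMoP replicate 2. Reads spliced into exon 4 from an exon other than exon 3 made up 13 of 26 and 32 of 66 in the knockout, and between 0 and 2 reads in each other library. Reads from exon 1 to exon 2, which holds 362 coding bp, were fewer too, 2 and 12 in the knockout against 42 and 45 in control Ly6Chi, while 14 and 38 reads left exon 1 for any exon in the knockout. Reads from exon 3 into exon 4, 13 and 34, and from exon 2 into exon 3 remained, so the loss of these exons from the RNA was partial. Over the whole gene the log2 change in the knockout was 0.15 ± 0.15 (SE), which did not pass limma's test (adjusted p = 0.597).

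**Figure D1:**
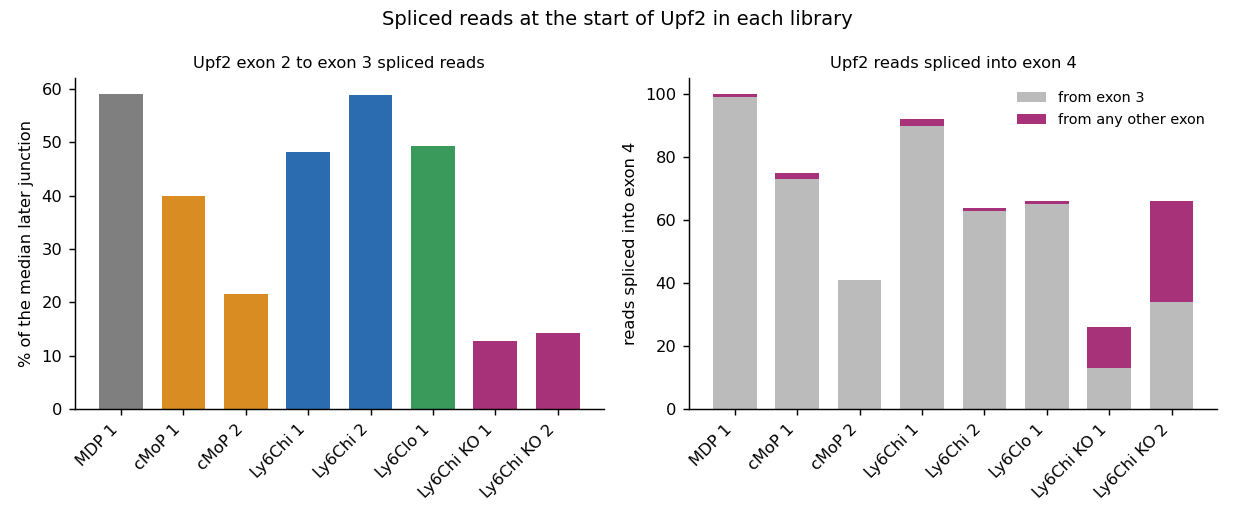
Spliced reads at the start of Upf2, 1 bar per library. Left, reads from exon 2 to exon 3 as a percentage of the median later junction, which stood at 12.7% and 14.2% in the knockout and between 21.5% and 59% elsewhere. Right, the number of reads spliced into exon 4 from exon 3 (grey) and from any other exon (purple).

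Across 65553 introns measured in every library, an intron with a retention ratio of at least 0.1 was counted as retained. Ly6Clo had the largest share, 8.11% (Wilson 95% interval 7.90 to 8.32), and MDP had 6.00% (5.82 to 6.19). Control Ly6Chi had 6.04% (5.86 to 6.22) and 5.72% (5.54 to 5.90), and cMoP 4.38% (4.22 to 4.53) and 1.52% (1.43 to 1.61). The knockout libraries, whose tables have another intron list than the other 6, had 3.18% (3.05 to 3.32) and 3.76% (3.62 to 3.91). The mean of 5.88% ± 0.225 (SD, n = 2) in Ly6Chi lay above 2.95% ± 2.02 in cMoP and 3.47% ± 0.411 in the knockout. An exact permutation test of each difference gave a two-sided p of 0.333, the smallest that 2 libraries against 2 allow. The libraries also differed in how far their spliced reads leaned to the 3′ end of genes. The median log2 ratio of 3′ to 5′ spliced reads was 0.66 in MDP, 1.01 and 1.45 in cMoP, 0.61 and 0.70 in Ly6Chi, 0.66 in Ly6Clo, and 1.36 and 1.00 in the knockout. In each replicated group the library with the higher ratio had the lower share of retained introns. With only introns without a warning this order turned in Ly6Chi (5.50% in replicate 1 and 5.83% in replicate 2).

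**Figure D2:**
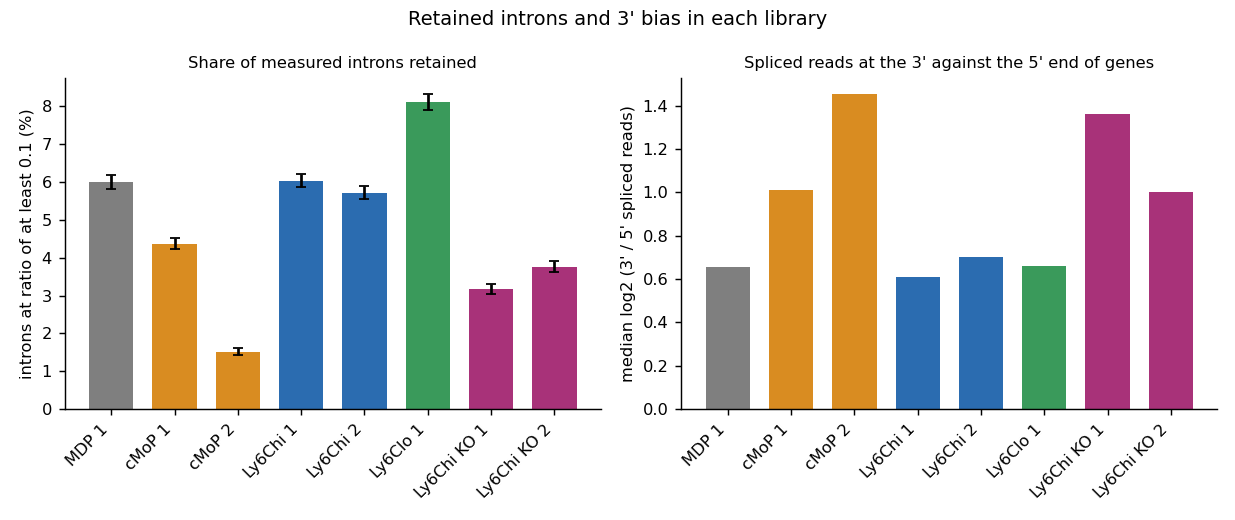
Left, the percentage of introns with a retention ratio of at least 0.1 in each library, with Wilson 95% intervals as error bars; cMoP replicate 2 was lowest at 1.52% and Ly6Clo highest at 8.11%. Right, the median log2 ratio of 3′ to 5′ spliced reads, which was highest in cMoP replicate 2 (1.45) and knockout replicate 1 (1.36).

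The rule for the introns with the highest mean ratio met 43 introns of 42 genes at a ratio of 1 in all 8 libraries, none with a spliced read, so that no order among them exists. It took introns of Bloc1s1, Hdac2, Sumo3, Pttg1 and Tnip1. Among introns with at least 10 spliced reads in every library, a choice made after the values were seen, the highest mean ratio was 0.767 in Tbrg4 (11:6615767–6616557, in the 3′ untranslated region). Others were 0.717 in Zc3h7a (16:11151326–11151865), 0.666 in Hmbox1 (14:64813420–64817016, 3′ untranslated) and 0.634 in Naip5 (13:100230785–100233339).

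From MDP to cMoP, the step that commits cells to the monocyte line, the granule protease list held the most rises and the progenitor and dendritic cell lists the most falls. Both cMoP libraries also leaned more to the 3′ end (1.01 and 1.45) than MDP (0.66), a difference that goes with the groups. The median gene stood at −0.28 (log2) in this comparison, and log2 changes here are given relative to it, ± SE, with 2 cMoP libraries against 1 of MDP. P-values of limma's test are for the change before this shift. Elane (ENSMUSG00000020125), neutrophil elastase, rose by 4.85 ± 0.21 (adjusted p = 0.00116), from 219 to 5230 ± 548 (SD) TPM, and Ly6c2 (ENSMUSG00000022584), the gene of the Ly6C antigen, rose by 4.77 ± 0.22 from 184 to 4196 ± 959 TPM. The growth factor gene Nrg1 (ENSMUSG00000062991) rose by 4.80 ± 0.21 (0.37 to 30.3 ± 0.891 TPM), the epidermal gene Dmkn (ENSMUSG00000060962) by 5.75 ± 0.40 and the Fc receptor gene Fcgr3 (ENSMUSG00000059498) by 4.63 ± 0.35. Flt3 (ENSMUSG00000042817), the cytokine receptor of early and dendritic progenitors, fell from 197 to 2.54 ± 2.34 TPM (−5.70 ± 0.59, adjusted p = 0.00941), and the desaturase gene Fads2 (ENSMUSG00000024665) from 70.9 to 1.92 ± 0.764 TPM. Mir142b and Mir6418, small RNAs with uncertain values, were at 44.3 and 22.2 TPM in MDP and listed at 0 in cMoP.

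Of 20 measured granule protease and cMoP genes, 9 rose and 0 fell, among them Prtn3 (2.25 ± 0.16), Gstm1 (3.48 ± 0.27) and Ms4a3 (4.22 ± 0.34); adjusted over the list alone, 14 rose and 1 fell (camera adjusted p = 2.5e-19; adjusted p = 0.198 with an estimated correlation). Of 30 lysosome and phagocytosis genes 5 rose, including the sialidase Neu1 (1.66 ± 0.15) and Cd63 (2.03 ± 0.29), and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.51e-07; adjusted p = 0.641 with an estimated correlation). The Ly6Chi list rose in 4 of 27 entries and fell in 1, or 7 and 4 adjusted over the list alone, with rises of haptoglobin Hp (3.28 ± 0.24) and the transcription factor Klf4 (2.49 ± 0.35, called in 7 of 13 settings). Its camera adjusted p was 0.000246, and adjusted p = 0.641 with an estimated correlation. Of 18 progenitor genes 7 fell, among them the homeobox gene Hoxa9 (−2.16 ± 0.22) and Cd27 (−3.54 ± 0.44, called in 8 of 13 settings), and 14 fell adjusted over the list alone (camera adjusted p = 9.89e-07; adjusted p = 0.641 with an estimated correlation). Dendritic cell markers fell in 5 of 11, or 9 adjusted over the list alone, with Itgax at −3.56 ± 0.31 and Cox6a2 at −3.88 ± 0.27 (camera adjusted p = 9.89e-07; adjusted p = 0.198 with an estimated correlation). Antigen presentation genes fell in 4 of 19, or 5 adjusted over the list alone: the class II genes Cd74 (−4.72 ± 0.40), H2-Aa (−4.12 ± 0.49), H2-Eb1 and H2-Ab1 (camera adjusted p = 0.0273; adjusted p = 0.879 with an estimated correlation).

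Markers of other cells moved with these groups. Of 10 B and plasma cell markers 4 fell, Cd22, Blnk, Ighd and Cd79a, and 8 fell adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.641 with an estimated correlation). Of 16 neutrophil markers 3 fell, S100a8, Mmp9 and Chil1, each called in at most 4 of its settings, and 11 fell adjusted over the list alone (camera adjusted p = 0.00299; adjusted p = 0.641 with an estimated correlation). In the Ly6Clo list Cebpb and Apoc2 rose and Itgax fell, the same 3 adjusted over the list alone. Irf7 fell among 30 interferon response genes (called in 3 of 13 settings) and Cd163 among 10 macrophage markers, each also the 1 fall adjusted over the list alone. None of the 32 cell cycle, 20 NMD factor, 30 NMD target, 24 amino acid and stress, 46 splicing regulator, 36 core spliceosome, 27 ribosome biogenesis or 29 inflammatory genes passed limma's test, over all genes or adjusted over the list alone. Nor did any of 18 p53 targets, 6 erythroid or 10 eosinophil, basophil and mast cell markers over all genes. Adjusted over the list alone, 2 p53 targets and 1 erythroid marker fell, and 1 of the last list rose and 1 fell. Camera called 4 of these lists higher, NMD targets (adjusted p = 0.0445), amino acid and stress (0.000626), inflammatory (0.000994) and ribosome biogenesis genes (0.0255), and splicing regulators lower (0.00162). With an estimated correlation these had adjusted p = 0.641, 0.641, 0.867, 0.917 and 0.641. The median and mean were negative while the test pointed up for NMD factors, core spliceosome, Ly6Clo and macrophage lists.

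Over all 13126 genes, 508 passed limma's test, 177 higher and 331 lower in cMoP, of which 476 changed by at least 2-fold. The split turned with the scaling, to 408 higher and 295 lower with median centring and 494 and 379 with quantile normalisation, and a pseudocount of 0.1 gave 157 and 143. The count was 0 with only these groups fitted, where 1239 genes had an unadjusted p under 0.05. It was 4917 without cMoP replicate 1, 799 without cMoP replicate 2, 120 without either Ly6Chi replicate, and 106 and 107 without knockout replicates 1 and 2.

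**Figure D3:**
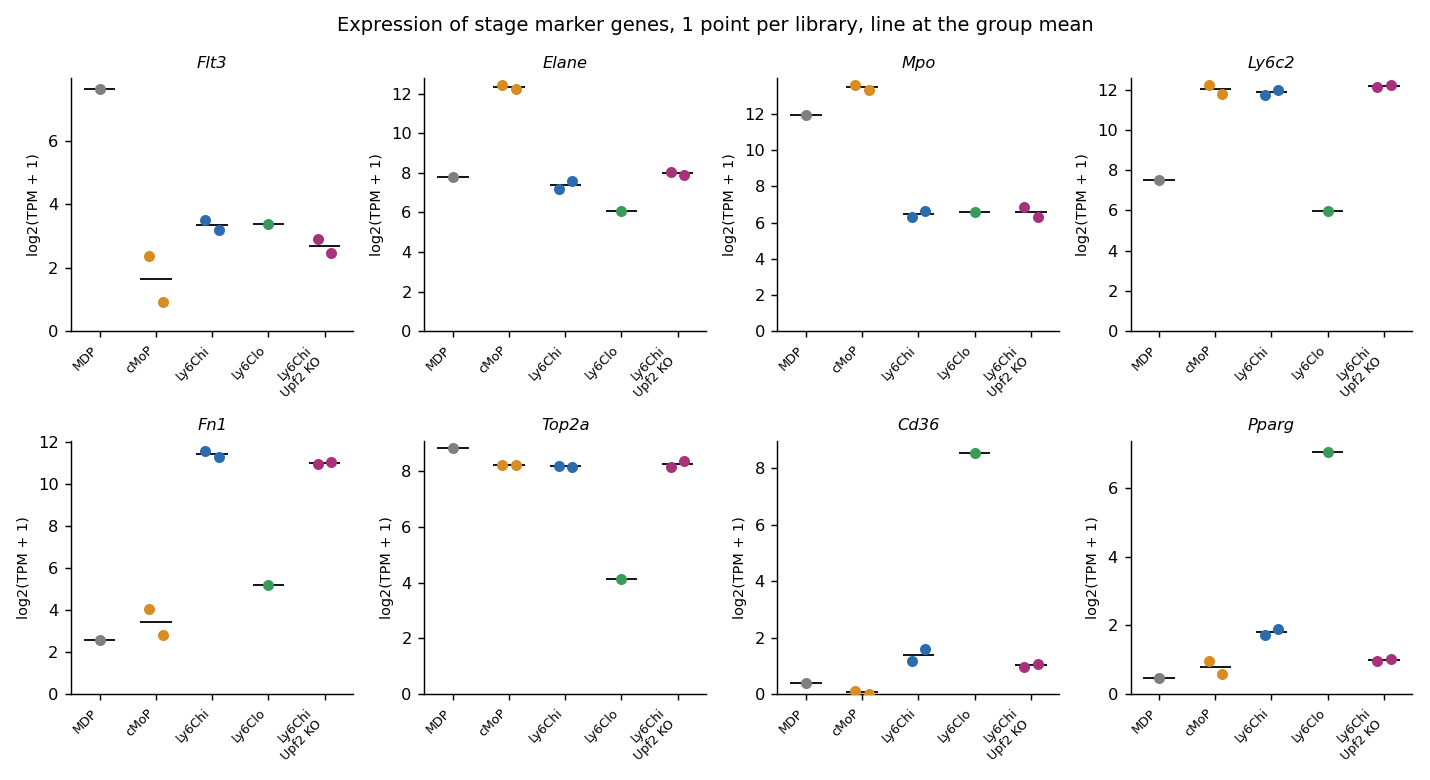
Log2(TPM + 1) of 8 stage marker genes in the 5 groups, 1 point per library and a line at the group mean of these values. Elane stood at 5230 TPM in cMoP against 219 in MDP, Fn1 at 2752 in Ly6Chi against 10.8 in cMoP, and Cd36 at 372 in Ly6Clo against 1.62 in Ly6Chi.

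In retention, no intron passed edgeR's test between cMoP and MDP: 0 of 48132, with 4020 at an unadjusted p under 0.05, and DESeq2 and limma on intron depth gave 0 as well. The median intron lay at −0.39 on the log2 scale of boundary to spliced reads, with both cMoP libraries more 3′ leaning than MDP. Once this shift was removed by TMM scaling, 9 introns passed, 8 higher and 1 lower. Introns from this scaled fit, in this and later comparisons, were picked by the rule for called introns, after the counts had been seen. The higher ones included an intron of Zfp207 (11:80395876–80398415), a zinc finger gene, called in 2 of 20 settings, with a retention ratio of 0.487 in MDP and 0.606 ± 0.0873 in cMoP (log2 3.44 ± 0.58), whose reads were one-ended. All 8 were one-ended. The lower one, in the histone variant gene H2afy (13:56088343–56096123), went from a ratio of 0.0724 to 0.0162 ± 0.0155 (log2 −2.06 ± 0.39). Unscaled, the count was 4944 without cMoP replicate 1 and 9 without cMoP replicate 2. Scaled, it was 29 without cMoP replicate 2.

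From cMoP to Ly6Chi monocytes, 2 libraries against 2, most genes of the Ly6Chi, Ly6Clo, interferon, lysosome and antigen presentation lists rose and most of the ribosome biogenesis, core spliceosome and granule protease lists fell. The cMoP libraries leaned more to the 3′ end (1.01 and 1.45) than Ly6Chi (0.61 and 0.70), which goes with these groups too. The median gene stood at 0.19 (log2), and log2 changes are again relative to it, while p-values of limma's test are for the change before this shift. Cd74 (ENSMUSG00000024610), the class II invariant chain, rose from 1.41 ± 0.813 to 755 ± 36.2 TPM (8.14 ± 0.33, adjusted p = 9.41e-05). Fibronectin Fn1 (ENSMUSG00000026193) rose from 10.8 ± 6.70 to 2752 ± 436 TPM (7.79 ± 0.39). The Src family kinase gene Fgr (ENSMUSG00000028874) rose by 7.34 ± 0.13, the phospholipase B-like gene Plbd1 (ENSMUSG00000030214) by 7.67 ± 0.18 and Sirpb1c (ENSMUSG00000074677), with close copies, by 7.68 ± 0.19. Myeloperoxidase, Mpo (ENSMUSG00000009350), fell from 11377 ± 1470 to 87.3 ± 14.2 TPM, 130-fold lower (−7.21 ± 0.22, adjusted p = 5.67e-05). Ms4a3 (ENSMUSG00000024681) fell 82.9-fold and Nkg7 (ENSMUSG00000004612) 54.1-fold, and Snord22 (ENSMUSG00000065087), uncertain, fell by 5.39 ± 0.74 on the log2 scale.

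No list called by camera from cMoP to Ly6Chi kept its call with an estimated correlation, where the inflammatory list had adjusted p = 0.632 and the others adjusted p = 0.412. Of 27 Ly6Chi entries 23 rose and 1 fell (24 and 1 adjusted over the list alone), with lysozyme Lyz2 62.9-fold and versican Vcan 256-fold higher (camera adjusted p = 1.27e-07). Of 23 Ly6Clo genes 19 rose and 0 fell, with the same counts adjusted over the list alone, among them Clec4a3 (7.10 ± 0.15) and Ear2 (5.92 ± 0.20; camera adjusted p = 5.49e-06). Interferon response genes rose in 28 of 30 and fell in 0, also adjusted over the list alone: Irf7, the master regulator of type I interferon, went from 1.12 ± 0.269 to 156 ± 27.4 TPM and Ifit3 from 0.07 to 47.6 ± 10.3 (camera adjusted p = 2.85e-10). Lysosome and phagocytosis genes rose in 27 of 30 and fell in 1 (28 and 1 adjusted over the list alone), such as the scavenger receptor Msr1 (439-fold) and Cd68 (8.71-fold; camera adjusted p = 1.27e-07). Antigen presentation genes rose in 16 of 19 and fell in 0, also adjusted over the list alone, with cathepsin Ctss 20.3-fold and H2-Aa 251-fold higher (camera adjusted p = 5.8e-05). Of 29 inflammatory and immediate-early genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), such as the chemokine Ccl6 (106-fold) and Tlr2 (7.29-fold; camera adjusted p = 0.0058). Of 18 p53 targets 10 rose and 2 fell (11 and 3 adjusted over the list alone), with the death receptor Fas 20.5-fold higher, and camera did not call the list (adjusted p = 0.0835).

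The same loss of the call, at adjusted p = 0.412 with an estimated correlation, holds for every falling list that camera called. Ribosome biogenesis genes fell in 26 of 27, also adjusted over the list alone: Nop56 from 479 ± 98.5 to 80.1 ± 3.20 TPM, Gnl3 11.2-fold and Nop58 8.06-fold (camera adjusted p = 6.5e-12). Core spliceosome genes fell in 23 of 36 and rose in 1, also adjusted over the list alone, with the Sm protein genes Snrpf (−1.68 ± 0.14) and Snrpd2 (−1.76 ± 0.15; camera adjusted p = 5.27e-06). Of 46 splicing regulators 16 fell and 6 rose, also adjusted over the list alone, among them Hnrnpa1 (−1.37 ± 0.13) and Srsf7 (−1.58 ± 0.18), and camera did not call the list (adjusted p = 0.0733). Progenitor genes fell in 12 of 18 and rose in 4 (13 and 4 adjusted over the list alone), with the stem cell factor receptor Kit 133-fold and Cd34 23.1-fold lower (camera adjusted p = 0.000397). Granule protease genes fell in 13 of 20 and rose in 3, also adjusted over the list alone, with Ctsg 33.2-fold and Prtn3 20.8-fold lower (camera adjusted p = 1.02e-05). Cell cycle genes fell in 13 of 32 and rose in 3, also adjusted over the list alone, led by the replication helicase genes Mcm6, Mcm2 and Mcm3 (−2.04, −2.16 and −2.07; camera adjusted p = 0.00486). Amino acid and stress genes fell in 12 of 24 and rose in 3 (13 and 3 adjusted over the list alone), with the serine synthesis gene Phgdh 23.6-fold lower (camera adjusted p = 0.003). NMD targets fell in 14 of 30 and rose in 7, also adjusted over the list alone, with the small RNA host genes Gas5 (−1.95 ± 0.13) and Snhg1 (−2.33 ± 0.20; camera adjusted p = 0.0242). Of 20 NMD factors 5 rose and 5 fell, 4 and 3 adjusted over the list alone: Pnrc2 rose (1.19 ± 0.15) and the exon junction genes Rnps1, Magoh and Eif4a3 fell (−1.19, −1.43 and −1.21).

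Markers of other cells moved as well. Neutrophil markers rose in 12 of 16 (13 adjusted over the list alone; camera adjusted p = 0.00142). Among them were Cd177 (40.1-fold) and Mmp8 (35.4-fold), which are also on the Ly6Chi list. Macrophage markers rose in 7 of 10 (7 rose and 1 fell adjusted over the list alone), such as Hmox1 (31.1-fold; camera adjusted p = 0.0136). Of 11 dendritic cell markers 6 rose and 1 fell, also adjusted over the list alone, and of 10 eosinophil, basophil and mast cell markers 1 rose and 4 fell (2 and 4 adjusted over the list alone). Of 10 B and plasma cell markers 1 rose and 2 fell (1 and 1 adjusted over the list alone), and of 6 erythroid markers Hba-a1 rose in 4 of 14 settings and none passed adjusted over the list alone. The neutrophil and macrophage calls too were lost with an estimated correlation (adjusted p = 0.412 for both). Before the shift to the median gene, the sign of the median or mean differed from the test's for NMD factors, B cell and eosinophil lists, none of which was called. Relative to the median gene, their medians were −0.200, 0.0254 and −0.366, and the test pointed down for each.

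**Figure D4:**
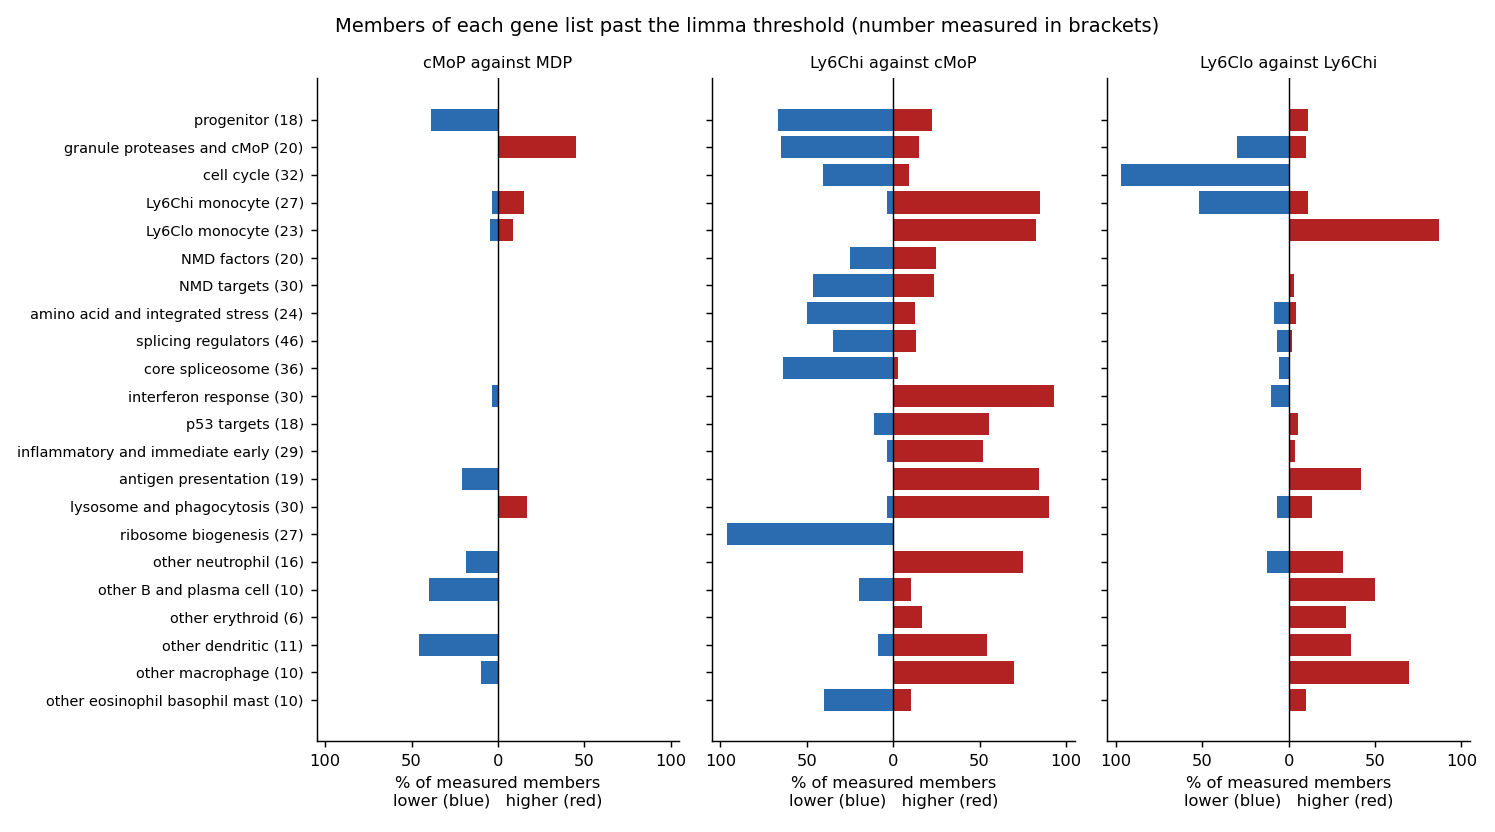
Percentage of the measured members of each gene list that passed limma's test, lower (blue, left) and higher (red, right), in the 3 stage comparisons, with the number measured in brackets. From cMoP to Ly6Chi 26 of 27 ribosome biogenesis genes were lower and 28 of 30 interferon genes higher, and from Ly6Chi to Ly6Clo 31 of 32 cell cycle genes were lower.

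Over all genes 7288 passed limma's test, 4235 higher and 3053 lower in Ly6Chi, of which 4260 changed by at least 2-fold. The split turned with the scaling, to 3354 higher and 4462 lower with median centring and 3695 and 4423 with quantile normalisation. Without Ly6Chi replicate 1 or 2 the count was 3774 or 4005.

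Between cMoP and Ly6Chi 7 of 48132 introns passed edgeR's test in retention, 2 higher and 5 lower in Ly6Chi. Both higher introns and 2 of the 5 lower ones were one-ended. The retention ratio changed by at least 0.1 in 0 of the higher and 1 of the lower introns. The first intron of Apoe (ENSMUSG00000002985), the apolipoprotein E gene, went from a ratio of 0.426 ± 0.0726 (n = 2) to 0.0201 ± 0.00606 (n = 2), at 7:19698474–19699010 in the 5′ untranslated region of Apoe-204. Its spliced reads went from 57 and 26 to 2328 and 3274 (log2 −5.59 ± 0.37, adjusted p = 0.000293, called in 20 of 20 settings), while Apoe rose from 11.4 ± 4.14 to 793 ± 90.9 TPM. Also lower were introns of H2-Ab1 (ENSMUSG00000073421, 17:34263406–34264760, coding, −5.09 ± 0.41), Ubtf (ENSMUSG00000020923, 11:102316474–102318847, 5′ untranslated, −3.61 ± 0.43), a transcription factor gene of ribosomal RNA, Chil3 (ENSMUSG00000040809, 3:106160534–106161173, coding, −3.36 ± 0.40) and the ribosomal protein gene Rpl21 (ENSMUSG00000041453, 5:146833567–146834183, 5′ untranslated, −2.27 ± 0.28). The intron of H2-Ab1 had a ratio of 0.0236 ± 0.00840 in cMoP and 0.0284 ± 0.0113 in Ly6Chi, so its fall lay in the counts at its ends and not in its coverage. Higher were introns of Adssl1 (ENSMUSG00000011148, 12:112632317–112632694, coding, 5.33 ± 0.35), whose right boundary went from 9 and 8 reads to 438 and 526, and Sema4d (ENSMUSG00000021451, 13:51734571–51763251, 5′ untranslated, 4.95 ± 0.45), whose left boundary went from 10 and 4 to 480 and 404.

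The median intron lay at 0.38 on the log2 scale, with cMoP more 3′ leaning (1.01 and 1.45) than Ly6Chi (0.61 and 0.70). Without the TMM scaling 5234 introns had an unadjusted p under 0.05. Once the shift was removed by TMM scaling 197 passed, 82 higher and 115 lower, including all 7, and DESeq2 called 15 and limma on intron depth 25. In the scaled fit an intron of Ogt (X:101652209–101653975), the O-GlcNAc transferase gene, was higher, from 0.261 ± 0.219 to 0.787 ± 0.0146 (2.76 ± 0.36). So were introns of Trip6 (5:137313709–137313959), from 0.615 ± 0.268 to 0.952 ± 0.0195, and Cdk16 (X:20696142–20696346), from 0.109 ± 0.0823 to 0.357 ± 0.0211. Lower were introns of immediate-early and chemokine genes: Ccl4 (11:83663574–83664293), from 0.479 ± 0.108 to 0.123 ± 0.0910, Ccl3 (11:83648681–83649201), from 0.316 ± 0.0721 to 0.149 ± 0.0803, Ier3 (17:35821929–35822037), from 0.234 ± 0.0339 to 0.0709 ± 0.0402, and the transcription factor Klf2 (8:72319150–72319425), from 0.458 ± 0.147 to 0.198 ± 0.0440. Introns with one-ended reads made up 22% of the 82 higher introns, counted in Ly6Chi, and 57.4% of the 115 lower ones, counted in cMoP. Over all tested introns the share was counted in the knockout libraries only (45.2%), so it gives no baseline here. Without the scaling the count was 6988 without cMoP replicate 1, 35 without cMoP replicate 2, 2 and 3 without Ly6Chi replicates 1 and 2, and 4 without either knockout replicate. Scaled, it was 66 without cMoP replicate 2.

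**Figure D5:**
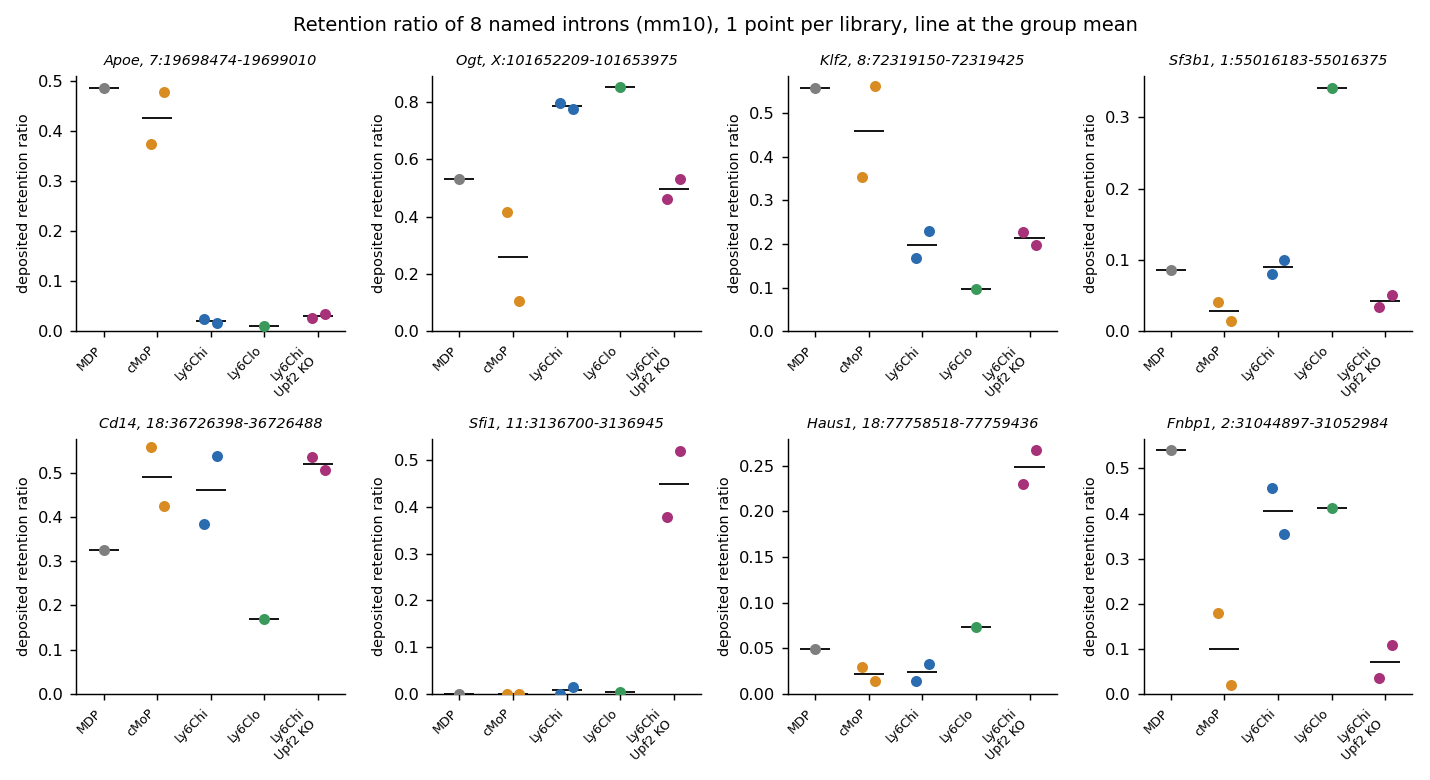
Deposited retention ratio of 8 named introns (mm10 positions in the titles) in the 5 groups, 1 point per library and a line at the group mean. The Apoe intron fell from a mean of 0.426 in cMoP to 0.0201 in Ly6Chi, and the Sf3b1 intron stood at 0.342 in Ly6Clo against 0.0809 and 0.101 in Ly6Chi. The Sfi1 and Haus1 introns were highest in the 2 knockout libraries.

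From Ly6Chi to Ly6Clo monocytes, the patrolling monocytes of the vessel wall, 31 of 32 cell cycle genes fell and 20 of 23 genes of the Ly6Clo list rose, with 1 Ly6Clo library against 2. Cd36 (ENSMUSG00000002944), the fatty acid scavenger receptor, rose from 1.62 ± 0.559 to 372 TPM (log2 7.17 ± 0.26, adjusted p = 0.000246). The integrin gene Itgax (ENSMUSG00000030789) rose 146-fold, the complement gene C1qa (ENSMUSG00000036887) 171-fold and Cd300ld3 (ENSMUSG00000069607) 106-fold. Mir142b, uncertain, was at 89.3 TPM and listed at 0 in both Ly6Chi libraries. Ly6c2 fell from 3748 ± 437 to 62.8 TPM (−5.87 ± 0.22, adjusted p = 0.000246), Fn1 78.5-fold, Vcan (ENSMUSG00000021614) 93.3-fold and the coagulation factor gene F13a1 (ENSMUSG00000039109) 32.6-fold.

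Of 32 cell cycle genes 31 fell, and all 32 adjusted over the list alone: Top2a, topoisomerase II alpha, from 288 ± 3.45 to 16.5 TPM, Cdk1 14.4-fold and survivin, Birc5, 23.6-fold (camera adjusted p = 9.37e-34; adjusted p = 0.252 with an estimated correlation). Of 23 Ly6Clo genes 20 rose (21 adjusted over the list alone), among them the nuclear receptor Pparg (52.1-fold), Eno3 (53.2-fold) and Dusp16 (135-fold; camera adjusted p = 7.34e-20; adjusted p = 0.274 with an estimated correlation). Of 27 Ly6Chi entries 14 fell and 3 rose (16 and 5 adjusted over the list alone), with S100a10 at −3.27 ± 0.19 (camera adjusted p = 2.14e-05; adjusted p = 0.474 with an estimated correlation). Antigen presentation genes rose in 8 of 19 (10 adjusted over the list alone), with Cd74 at 8563 against 755 ± 36.2 TPM and H2-Ab1 17.5-fold higher (camera adjusted p = 9.37e-05; adjusted p = 0.553 with an estimated correlation). Granule protease genes fell in 6 of 20 and rose in 2 (9 and 2 adjusted over the list alone), led by Prtn3 (−2.45 ± 0.16; camera adjusted p = 0.00612; adjusted p = 0.474 with an estimated correlation). Interferon response genes fell in 3 of 30, Ifit1, Rsad2 and Cmpk2, each called in at most 8 of 14 settings, and in 4 adjusted over the list alone (camera adjusted p = 4.69e-05; adjusted p = 0.557 with an estimated correlation). Of 46 splicing regulators 3 fell, Hnrnpd (−0.98 ± 0.17), Hnrnpa1 and Rbm3, and Son rose (0.79 ± 0.19), and 2 fell adjusted over the list alone. Of 36 core spliceosome genes Snrpa and Snrpf fell and none passed adjusted over the list alone (camera adjusted p = 0.0253; adjusted p = 0.756 with an estimated correlation).

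Lysosome genes went both ways, 4 up and 2 down of 30 (6 and 6 adjusted over the list alone), with Cd63 15.1-fold higher and Msr1 5.42-fold lower. Among 18 p53 targets Phlda3 rose (85.6-fold), the 1 also called adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.525 with an estimated correlation). Dusp2 rose among 29 inflammatory genes, also adjusted over the list alone, and Snhg15 among 30 NMD targets, with 0 adjusted over the list alone. The stress gene Ddit4 rose and Psat1 and Phgdh fell among 24 amino acid and stress genes, also adjusted over the list alone. Ly6a and Cdk6 rose among 18 progenitor genes (3 adjusted over the list alone). None of 20 NMD factors or 27 ribosome biogenesis genes passed limma's test, over all genes or adjusted over the list alone. The median or mean differed in sign from the test for NMD targets, splicing regulators and inflammatory genes, none called by camera.

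Lists of other cell types moved with the single Ly6Clo library as well. Neutrophil markers rose in 5 of 16 and fell in 2 (11 and 2 adjusted over the list alone), with Mmp9 18.8-fold and S100a8 2.51-fold higher (camera adjusted p = 0.000416; adjusted p = 0.553 with an estimated correlation). B and plasma cell markers rose in 5 of 10 (9 adjusted over the list alone), such as Cd22 (32.5-fold) and Cd79a (11.9-fold; camera adjusted p = 2.47e-06; adjusted p = 0.277 with an estimated correlation). Macrophage markers rose in 7 of 10 (8 adjusted over the list alone), such as C1qb (109-fold; camera adjusted p = 1.73e-06; adjusted p = 0.378 with an estimated correlation), and dendritic cell markers in 4 of 11 (6 adjusted over the list alone), such as Cd209a (168 against 16.8 ± 0.191 TPM; camera adjusted p = 0.000206; adjusted p = 0.274 with an estimated correlation). Erythroid markers rose in 2 of 6, Car1 and Car2, and 1 of 10 eosinophil, basophil and mast cell markers, Prss34, rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0129 and 0.0253; adjusted p = 0.553 with an estimated correlation for both). Some lists had too few measured genes for a list test. Of T and NK cell markers, Nkg7 and Klrd1 were measured, and Klrd1 rose 16.5-fold. Itga2b, the measured megakaryocyte and platelet gene, was at 2.48 against 0.87 ± 0.127 TPM (0.90 ± 0.20, adjusted p = 0.0393).

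Over all genes 1708 passed limma's test, 774 higher and 934 lower in Ly6Clo, of which 1395 changed by at least 2-fold. The count was 3683 and 3654 without cMoP replicates 1 and 2, 587 and 609 without Ly6Chi replicates 1 and 2, and 942 and 949 without knockout replicates 1 and 2. It was 3590 with no expression filter, 71.6% of them higher.

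In retention, 0 of 48132 introns passed edgeR's test between Ly6Clo and Ly6Chi, with 2391 at an unadjusted p under 0.05. DESeq2 gave 0 and limma on intron depth 15, all higher in Ly6Clo. The median intron lay at 0.11, and the 3′ lean was alike, 0.66 in Ly6Clo against 0.61 and 0.70. Once the shift was removed by TMM scaling 30 passed, 10 higher and 20 lower. An intron of Sf3b1 (1:55016183–55016375), itself a core splicing factor gene, had a ratio of 0.342 in Ly6Clo against 0.0809 and 0.101 in Ly6Chi (1.87 ± 0.36). The phosphate carrier gene Slc25a3 (10:91122332–91123557) had 0.337 against 0.130 and 0.137, and the kinase gene Map2k1 (9:64212731–64214398) 0.126 against 0.0266 and 0.0195. Lower in Ly6Clo were introns of the endotoxin co-receptor gene Cd14 (18:36726398–36726488), at 0.169 against 0.383 and 0.538, the kinase gene Sik1 (17:31850850–31850940), at 0.104 against 0.253 and 0.481, and the clock gene Per1 (11:69102753–69102824), at 0.0298 against 0.189 and 0.336. Unscaled, the count was 208 and 202 without cMoP replicates 1 and 2, 0 without any other replicate, and 423 with only these groups fitted (334 higher and 89 lower). Scaled, it was 327 without cMoP replicate 2, 180 higher and 147 lower, so the side with more introns turned.

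A test over the 4 control stages called 6 introns, those of Apoe, Adssl1, Sema4d, H2-Ab1, Ubtf and Chil3, with 4438 at an unadjusted p under 0.05. It called 514 with TMM scaling and 1 with a read minimum of 50.

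The knockout was set against control Ly6Chi monocytes, 2 libraries each, to see which genes and introns differ where part of the Upf2 RNA skips its first coding exons. In expression 1 of 13126 genes passed limma's test, while 1910 (14.6%) had an unadjusted p under 0.05. In simulated data 4.74% to 4.94% of unchanged genes did. Those data held no shift common to a library, so the larger share cannot be assigned to the knockout. The gene that passed, Gm27517 (ENSMUSG00000098265), an unnamed gene model outside the rule, was at 9.17 ± 0.933 TPM in the controls and listed at 0 in the knockout (adjusted p = 0.0323, called in 3 of 15 settings). The median gene stood at −0.12 (log2), and log2 changes are given relative to it, while p-values of limma's test are for the change before this shift. None of the 20 NMD factors passed, with Upf1 at 0.15 ± 0.15, Upf3b at 0.01 ± 0.21, and Smg1, the kinase of Upf1, at 19.5 ± 9.24 against 45.2 ± 5.76 TPM (−1.12 ± 0.42, adjusted p = 0.336). None of the 30 NMD targets passed, with Gas5 at 0.42 ± 0.13, Snhg1 at 0.59 ± 0.20 and Atf4 at 0.33 ± 0.22 (adjusted p = 0.349, 0.347 and 0.624). In simulated data the test found 36% of 2-fold changes, so smaller ones were mostly beyond this design.

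Interferon response genes were the list with the most members called adjusted over the list alone, 9 of 30, all lower in the knockout, and 0 over all genes. Ifit3 was at 0.295 times and Rsad2 at 0.251 times the control level, and Irf7 at 93.8 ± 1.69 against 156 ± 27.4 TPM. The list's median was −0.44 relative to the median gene (camera adjusted p = 6.82e-06; adjusted p = 0.874 with an estimated correlation). The knockout libraries also leaned more to the 3′ end than the controls (1.36 and 1.00 against 0.61 and 0.70), a difference that goes with the groups. Camera also placed the cell cycle list higher (adjusted p = 0.00272) and splicing regulators lower (adjusted p = 0.0454), with no member of either called, and each had adjusted p = 0.874 with an estimated correlation. Adjusted over the list alone, 1 granule protease gene and 1 Ly6Chi gene were higher, and 1 dendritic cell and 1 macrophage marker lower. No member of the other lists passed, over all genes or adjusted over the list alone. Before the shift to the median gene, the median, mean and test differed in sign for NMD factors, p53 targets, antigen presentation genes and neutrophil markers, none called. Relative to the median gene, their medians were 0.113, −0.00453, 0.156 and 0.0725, and the test pointed up for each. Among genes chosen after their values were seen, Lyz1, with its close copy Lyz2, was at 126 ± 35.8 against 26.4 ± 5.18 TPM and the macrophage gene Siglec1 at 2.38 ± 0.856 against 12.8 ± 1.92, each with an adjusted p of 0.298.

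In retention, 1 of 48132 introns passed edgeR's test between knockout and control, and 3342 had an unadjusted p under 0.05. It is the first intron of Cpsf2 (ENSMUSG00000041781, 12:101976135–101981913, 5779 bp, 5′ untranslated), a gene of the cleavage and polyadenylation complex. Its left boundary reads went from 0 and 2 to 156 and 160 and its right ones from 1 and 1 to 0 and 1 (log2 6.53 ± 0.56, adjusted p = 0.00777, called in 10 of 15 settings). Its retention ratio was near 0.004 in both groups, and an exon of another gene lies on the opposite strand there, so the source of these reads is uncertain. The knockout tables also have an intron list of their own, a difference that goes with the groups. The median intron lay at −0.32, with the knockout more 3′ leaning (1.36 and 1.00) than control Ly6Chi (0.61 and 0.70).

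Once this shift was removed by TMM scaling 62 introns passed, 50 higher and 12 lower in the knockout, and 33 of the 50 (66%) were one-ended, against 45.2% of those tested. Spanned from both ends were introns of Sfi1 (11:3136700–3136945), a centrosome gene with a ratio of 0 and 0.0152 in control and 0.378 and 0.521 in the knockout, and Haus1 (18:77758518–77759436), a spindle gene at 0.0145 and 0.0330 in control and 0.230 and 0.267 in the knockout. Stk35 (2:129800847–129801403) went from 0.00564 ± 0.00386 to 0.210 ± 0.0834, Tep1 (14:50845174–50845415), a telomerase-associated gene, from 0.0109 ± 0.00302 to 0.127 ± 0.0337 and Tkfc (19:10597022–10597309) from 0.00462 ± 0.000331 to 0.125 ± 0.0411. Lower in the knockout were introns of Fnbp1 (2:31044897–31052984), from 0.406 ± 0.0720 to 0.0714 ± 0.0508, Hmbox1 (14:64817137–64822053), from 0.690 ± 0.0435 to 0.269 ± 0.144, and Tmc6 (11:117774367–117775007), from 0.297 ± 0.0597 to 0.0768 ± 0.00950. DESeq2 called 5 introns and limma on intron depth 0. Unscaled, the count was 464 and 435 without cMoP replicates 1 and 2, 56 and 53 of them higher, 392 with only these groups fitted (48 higher and 344 lower), and 0 without any 1 Ly6Chi or knockout replicate. Scaled, it was 218 without cMoP replicate 2, 115 higher and 103 lower, and 110 with the right boundary alone, 68 higher and 42 lower, so the surplus of higher introns did not hold in size.

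Introns of listed genes were tested for a surplus of calls with Fisher's exact test, and no list passed without scaling (lowest adjusted p = 0.129). In the scaled fit from cMoP to Ly6Chi, inflammatory and immediate-early genes held 7 of 31 tested introns among the lower ones (adjusted p = 1.85e-11), lysosome genes 4 of 131, the Ly6Chi list 3 of 125 and the Ly6Clo list 2 of 62. Among the higher ones core spliceosome genes held 4 of 319 and lysosome genes 3 of 131. From MDP to cMoP interferon genes held 3 of 70 among the higher ones, and from Ly6Chi to Ly6Clo antigen presentation genes held 3 of 70, granule protease genes 2 of 71 and lysosome genes 2 of 131 among the lower ones. Introns of 1 gene are not independent, so these p-values are too small.

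Across 6759 genes, the retention change of a gene correlated weakly and negatively with its expression change. Spearman's rho was −0.0750 from MDP to cMoP, −0.135 from cMoP to Ly6Chi, −0.0847 from Ly6Chi to Ly6Clo and −0.0308 in the knockout, with permutation adjusted p = 1.33e-05 for the first 3, the smallest the permutations allow, and 0.0115. Pearson's r was −0.0440, −0.100, −0.0166 and −0.0348 (adjusted p = 0.00064, 4e-05, 0.172 and 0.00568). With TMM scaling rho was −0.00797, −0.0323, −0.0443 and −0.00431 in the same order (adjusted p = 0.684, 0.0161, 0.0014 and 0.724). Pearson's r with TMM scaling turned positive in the 3 stage comparisons, at 0.0372, 0.0304 and 0.0695, and was −0.00127 in the knockout. Genes are not independent replicates, and spliced reads enter both measures. The 5 genes with a fallen intron from cMoP to Ly6Chi had a median log2 expression change of 4.34, against 0.22 over all genes, and in the scaled fit 90 such genes had 0.96. The 2 genes with a risen intron also lay above all genes, at 1.48, and in the scaled fit 62 such genes had 0.07.

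By length, the 5 fallen introns from cMoP to Ly6Chi had a median of 640 bp and the 2 risen ones 14529.5 bp, against 1277 bp of all tested, and neither differed by a permutation test (p = 0.376 and 0.0627). In the scaled fit the 82 higher introns were shorter, at 623 bp (permutation p = 0.00032), and the 115 lower ones longer, at 2213 bp (p = 0.00036). The 50 higher introns of the knockout were longer, at 3560.5 bp (permutation p = 2e-05). These sets of 82, 115 and 50 introns lie in 63, 90 and 39 genes. Introns of 1 gene are not independent, so these p-values can be too small.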

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

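The tests on antisense-marked introns, on one-ended reads and on the 3′ lean within groups were chosen only after the results were seen, and those on cMoP replicate 2 and on opposite-strand exons before.

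Introns marked as overlapping or lying near an antisense gene stood outside the comparisons and showed a signal of their own: with introns of every class in the test, 79 of 14789 were called higher in the knockout and 0 lower, against 9 of 48132 unmarked introns. The share called higher was 28.6 times as large among the marked introns. This cannot decide whether a change in the knockout acts on introns whatever lies antisense to them. The value was already in view when the test was set, and a share past a threshold also depends on read numbers and spread. Reads counted without regard to strand in the knockout tables may account for the 79 calls and cannot be told apart from other causes. In introns that overlap an antisense gene the median log2 change was 0.153 above unmarked introns in the knockout, short of the 0.3 the test asked for. Between Ly6Clo and Ly6Chi, whose tables are of 1 kind, it was 0.0280 above them. Over all marked introns the differences were 0.109 and 0.0881. For the 50 unmarked introns that were higher in the knockout after TMM scaling, the values that both technical explanations need are there, more clearly for strand: 9 have an exon on the opposite strand, 12.2 times the share of the other tested introns (711 of 48082, Fisher's exact p = 5.17e-08), and 66% (exact 95% interval 51.2 to 78.8) have one-ended reads, against 45.2% of all tested introns, as reads crossing an alternative exon end could give. The 50 introns lie in 39 genes and introns of 1 gene are not independent, so this p-value can be too small and the interval too narrow. The knockout of Upf2, which the design names, stays open and untested for all 50, since reads from the opposite strand or from an alternative exon end could differ with it too.

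The share of retained introns was lower in the cMoP and knockout libraries, and cMoP replicate 2 had the fewest boundary reads per spliced read, with a median log2 ratio −0.65 against replicate 1. Fewer background reads that do not depend on expression, such as DNA, were tested for that library. The introns with the fewest and the most spliced reads shifted alike, with a difference of −0.000642. These values argue against background that makes up more of the boundary reads where spliced reads are few. Background that made up most boundary reads in both sets would shift them alike too, so it stays open. The 3′ biased coverage of cMoP replicate 2 cannot be told apart from other causes. The test set beforehand looked for the larger fall near the 5′ end of genes. The fall was larger near the 3′ end (−0.83 against −0.28, a difference of 0.542), which met neither bound. Over the libraries, 3′ biased coverage may contribute, since in 3 of 3 replicated groups the more biased library had the lower share of retained introns, an order that chance gives with 12.5%. With only introns without a warning the order turned in Ly6Chi, to 5.50% in replicate 1 and 5.83% in the more biased replicate 2. In the main setting the 4 least biased libraries had at least 5.72% and the 4 most biased at most 4.38%, so that stage and the knockout of Upf2, both untested, and the bias go together. The knockout tables also differ in kind from the other 6, which cannot be told apart from the knockout either.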

How the results depend on the processing

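Alternatives chosen only after the data were seen were the tests with array weights, without both cMoP libraries, with the right boundary alone, with the doubled smaller boundary, with a mean ratio of at least 0.05, with the 6 control libraries, and every scaled one other than the counts per comparison and over the stages. Every called gene chosen by the rule kept its sign in every setting run: 39 of 39 from MDP to cMoP, 88 of 88 to Ly6Chi and 63 of 63 to Ly6Clo. So did the 1 called in the knockout, which lies outside the rule. The groups compared did not overlap for any of these genes, so only quantile and median scaling could have turned a sign. A kept sign does not mean that the call was kept. Of the called introns 5 of 7 and 0 of 1 kept their sign in every setting. Sema4d turned to −1.17 and Cpsf2 to −0.22 with limma on intron depth, and H2-Ab1 to 1.99 with the doubled smaller boundary. With these counts and libraries 0% of 2-fold retention changes were found in simulated data, and whether depth or the number of libraries sets that limit was not tested. Except where fewer libraries or genes entered, the cause of each difference was not tested.

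Leaving out 1 replicate at a time gave expression counts from 106 to 4917 (MDP to cMoP), 3774 to 8794 (cMoP to Ly6Chi), 587 to 3683 (Ly6Chi to Ly6Clo) and 0 to 0 (knockout), against 508, 7288, 1708 and 1. The lone library left in a group was assumed to vary like the others. Expression counts from MDP to cMoP were 300 with a pseudocount of 0.1, 2348 with no filter, 269 with at least 5 TPM, 873 with quantile normalisation, 229 with array weights and 0 with only the 2 groups. From Ly6Chi to Ly6Clo they were 3590 with no filter, 2617 with quantile normalisation, 3293 with only the 2 groups, 3643 without the cMoP libraries and 3177 with array weights. In the knockout they were 0 with a pseudocount of 0.1, at least 5 TPM, only the 2 groups or no cMoP libraries, 3 with quantile normalisation and 16 with array weights. Whether the replicate numbers pair libraries across groups is not known, and they were treated as unpaired. The differences between replicates did not correlate across groups (r from −0.136 to 0.063 in expression), which cannot decide it with so few libraries. With a replicate block all the same, the expression count was 6331 from cMoP to Ly6Chi and 0 in the knockout, and the retention counts were 5 and 1. From cMoP to Ly6Chi the expression count stayed within 1.5 times the main one in every alternative other than leaving out a Ly6Chi replicate.

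Retention counts without 1 replicate ran from 0 to 4944, 2 to 6988, 0 to 208 and 0 to 464 in the 4 comparisons, in the order above, against 0, 7, 0 and 1. With TMM scaling they were 9, 197, 30 and 62, with only the 2 groups 2, 2, 423 and 392, with TMM scaling and the right boundary alone 21, 214, 34 and 110, and with TMM scaling without cMoP replicate 2, the most 3′ biased library, 29, 66, 327 and 218. From cMoP to Ly6Chi and in the knockout, they were 11 and 90 with introns of every class, 3 and 3 with introns without a warning, 25 and 0 with limma on intron depth (15 from Ly6Chi to Ly6Clo), 15 and 5 with DESeq2, 23 and 8 with the right boundary alone, 1 and 0 with the doubled smaller boundary, and 3 and 3 with a mean ratio of at least 0.05. With TMM scaling and that minimum they were 21 and 4, and 20 from Ly6Chi to Ly6Clo. From cMoP to Ly6Chi a read minimum of 50 gave 1 and the 6 control libraries 4, and in the knockout a read minimum of 10 gave 2. Over the stages a read minimum of 50 gave 1 and TMM scaling 514, against 6.

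The lists called by camera numbered 13, 15, 14 and 3 in the 4 comparisons and 0 in each with an estimated correlation. Lists with a surplus of called introns numbered 0 without scaling and 1, 5 and 3 in the stage comparisons with TMM scaling. Spearman's rho of retention and expression changes was −0.00797, −0.0323 and −0.0443 in the stage comparisons with TMM scaling. In the knockout it was −0.00431 with TMM scaling, −0.0174 with a read minimum of 50 and 0.0167, turned in sign, with the intron of highest ratio per gene. The median length of introns higher in Ly6Chi than in cMoP was 378 bp with a read minimum of 50 and 623 bp with TMM scaling, now shorter than the tested introns, and that of the lower ones 2213 bp with TMM scaling, now longer. For the knockout it was 3560.5 bp. The share of retained introns was higher in Ly6Chi than in cMoP by 2.93 points, and by 6.37, 0.876, 2.86 and 3.17 with ratios of at least 0.05 or 0.2, a read minimum of 50 and no warning. In the knockout it differed by −2.41 points, and by −5.47, −0.655, −2.31 and −2.57 in that order.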

Other observations

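Both tests in this part were chosen only after the results were seen. The neutrophil granule genes S100a9, Ngp and Camp, picked after their values were seen, had their highest level in the Ly6Clo library. S100a9 was at 2183 TPM in Ly6Clo, 626 ± 138 in Ly6Chi, 109 ± 62.0 in cMoP and 673 in MDP. Ngp was at 517, 115 ± 39.8, 20.5 ± 16.6 and 160 TPM in the same order, and Camp at 255, 55.7 ± 19.4, 11.1 ± 8.97 and 74.9. None of these 3 passed limma's test between Ly6Clo and Ly6Chi (adjusted p = 0.0786, 0.118 and 0.110), and Cd177 and Mmp8, also on the neutrophil list, were at 33.8 and 28.2 TPM in Ly6Clo against 241 ± 53.5 and 148 ± 4.41 in Ly6Chi.

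Markers of other blood cells were higher in the Ly6Clo library, with list medians (log2) of 1.65 for neutrophils, 1.48 for B and plasma cells, 1.82 for erythroid cells, 1.21 for dendritic cells, 1.81 for macrophages and 0.65 for eosinophils, basophils and mast cells. A first test of a lower share of monocytes among cells of every other type asked for a median above 0.5 in each list and was met (lowest 0.65), and it was replaced, after that result was seen, by a test that also asks whether the lists rose alike. They moved apart, the lower quartile of the erythroid list lying 0.904 above the upper quartile of the eosinophil list. This cannot decide the question, because these lists were picked for their highest and lowest median. Genes that are low, or already read in Ly6Chi, would also change less on this scale under a uniform dilution. A lower share of monocytes therefore stays open. B cells among the sorted cells cannot be told apart from other causes, because the test run, in which 100% of the measured markers (10 of 10) were higher than in both Ly6Chi libraries, restates the pattern and supports nothing. Ighm, the most abundant, was at 699 TPM against 503 ± 3.34 in Ly6Chi, 633 in MDP and 335 ± 150 in cMoP, the labels name no gate that would remove B cells, and expression of these genes by Ly6Clo monocytes themselves was not tested.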
